A study of Caenorhabditis elegans with 2 samples.

How the data were processed

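ChIP-seq of GFP-tagged TTX-3 was performed on whole late embryos in 2 biological replicates, per the labels. The authors deposited peak lists on the ce10 and ce11 builds: 1 list of 30000 peaks and background regions for each replicate, 1 for the replicates pooled, and 1 of optimal IDR-thresholded peaks. Per the deposited file descriptions, each replicate's list was made from that replicate's alignments and a control alignment file shared by both replicates, the pooled list from the alignments of both, and the optimal list from the replicate and pooled lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited lists give each peak a signal value, the peak strength assigned by the authors' caller with the control as its background, which has no stated scale between lists. They also give −log10 of a q-value, deposited by the authors, which lay between 1.40 and 1.51 in the optimal list, and a summit position. The control was not analysed here. Signal was used only to rank and describe peaks within a list and to compare the replicates at the same peaks.

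The lists hold no read counts, so sequencing depth is unknown and no precision follows from it. The median region was 450 bp wide in the pooled list and 254 bp among the 100 strongest optimal peaks. All 700 optimal peaks on ce11 are entries of the pooled list, and they are its 700 strongest by signal. Hence an optimal peak need not be in both replicates: 23 had no summit of replicate 1 within 100 bp and 31 none of replicate 2, 20 of them nuclear. Exact intervals and p-values over peaks or genes cover counting error only and not the spread between embryos.

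Peaks of the ce11 lists were placed on the WBcel235 genome and the Ensembl 115 annotation. No peak end exceeded the length of its chromosome. Of the annotated genes, 2811 had no name, and 2760 of these were given the RefSeq symbol of the gene with the same coordinates on the same assembly; identifiers are printed for the others. A gene had a peak when an optimal summit lay between 1000 bp upstream and 300 bp downstream of the 5' end of any of its protein-coding transcripts. Background peaks were the 15000 weakest peaks of the pooled list without an overlap with an optimal peak, 14941 in all. Summit location was assigned to coding exon, 5' UTR, 3' UTR, intron, other gene or intergenic, in that order.

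The following choices were made before the data were examined: the window, the background, the tests and their alternatives, the 17 gene lists, and the rule for the genes named. The rule took the genes at the 20 strongest optimal peaks, all members of the AIY and the AIA and NSM lists, the 4 members with the strongest peak of each other list that passed, and the 5 6-mers of lowest p. In the intestine list 1 of its symbols was not found in the annotation and was left out, which leaves 14 genes. Replicate overlap was tested by 1000 random draws from the whole replicate 1 list (one-sided permutation). Promoter location, gene lists, TAATTA and 6-mers were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 17 lists and over the 2080 6-mers left after merging reverse complements. Sequence windows extended 50 bp to each side of the summit. The share of peaks on X was compared with the background share by a two-sided exact binomial test. Intervals of shares are exact (Clopper-Pearson) and those of odds ratios exact conditional intervals, at 95%. Correlation intervals come from 1000 bootstrap draws over peaks. With 1 group no test between groups was possible.

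The alternatives were the ce10 lists, other distances and windows, the whole pooled list as background, a background matched on GC content, random gene lists matched on upstream length (10000 for each list), and the stronger 350 optimal peaks. The GC matching was changed after its first result was seen: up to 5 background peaks per optimal peak left the background poorer in G and C, so 1 peak per optimal peak was drawn within 2 bases of its number of G and C, and both versions are reported. Leaving out a replicate meant taking the 700 strongest peaks of the other replicate. The statistics were tested on simulated data. With 20 6-mers planted in 10% of windows, for the comparison of 6-mers at optimal summits, 19 were called among the 2080, and none was called with nothing planted. Over 20 random sets of background peaks, 4 list calls were made among the 17 lists of each set. A simulated replicate list that shared 40% of its peaks gave an overlap of 40.0%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.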

Results

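The chromosomal sites recovered with TTX-3 were profiled in whole late embryos of Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). TTX-3 is a LIM homeodomain transcription factor that specifies the AIY interneurons of the thermosensory circuit and also acts in the AIA and NSM neurons. The transgenic strain expressed TTX-3 fused to GFP, an antibody against GFP was used, and embryos were collected 4 hours after synchronization by bleaching. There was 1 group of 2 biological replicates and no second condition, so the comparisons set the replicates against each other and the peaks that passed the authors' reproducibility filter against weaker peaks. Sequencing depth is unknown, since the peak lists carry no read counts. Each replicate's list and the pooled list held 30000 regions ranked by the authors' peak signal, down to the level of background. The list that passed the authors' irreproducible discovery rate (IDR) filter, called optimal peaks here, held 700 regions on the ce11 build and 695 on ce10. Positions below are on ce11, whose coordinates are those of WBcel235.

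The first question was how far the replicates agreed. Of the 700 strongest peaks of replicate 1, 413 (59.0%) had a summit within 100 bp of one of the 700 strongest peaks of replicate 2. The strongest nuclear peak was the same in both lists, next to K12H4.5, with a signal of 393 in replicate 1 and 388 in replicate 2, and the peak in an intron of frm-7 had 363 and 386. The strongest replicate 1 peaks that replicate 2 lacked were mitochondrial: replicate 1 held 21 peaks on the mitochondrial genome, 20 of them among its 700 strongest, and replicate 2 held 0 in its whole list. Random draws of 700 summits from the replicate 1 list shared 1.91% with replicate 2 on average and 3.71% at most, which gave a one-sided permutation p of 0.001, the smallest that 1000 draws can give. At the optimal peaks, signal was found in both replicates for 647 of the 700, and the Spearman correlation across these peaks was 0.678 (bootstrap 95% interval 0.624 to 0.726), with a Pearson correlation of log2 signal of 0.756. Both correlations are across peaks, which are not replicates. The correlation was 0.754 when summits had to lie within 50 bp.

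**Figure D1:**
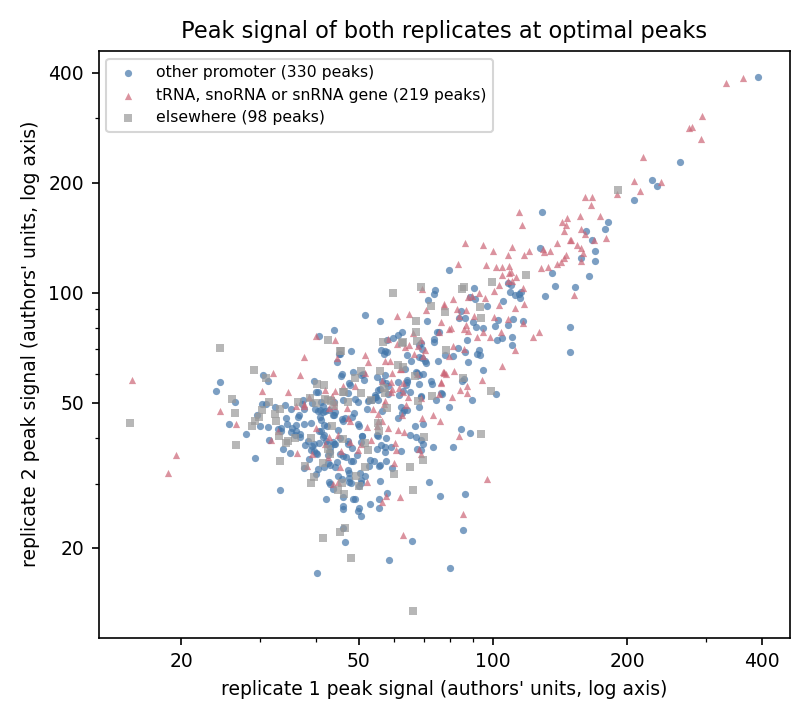
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, at the 647 optimal peaks found in both replicates; each point is 1 peak, coloured by whether its summit lies within 100 bp of a tRNA, snoRNA or snRNA gene, in another promoter window, or elsewhere. The strongest peaks lie close together in both replicates, and the scatter widens among the weaker ones (Spearman correlation 0.678).

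The optimal peaks lay mainly at promoters of protein-coding genes and at genes for small noncoding RNAs. In all, 428 of the 700 summits (61.1%) fell between 1000 bp upstream and 300 bp downstream of an annotated 5' end of a protein-coding transcript, against 4329 of 14941 background peaks (29.0%). The odds ratio was 3.86 (exact 95% interval 3.29 to 4.53, two-sided Fisher's exact test p = 4.75e-66). By annotation, 54.6% of optimal summits were intergenic, 27.4% lay in introns and 2.43% in coding exons, against 37.4%, 44.1% and 10.4% of background summits. A count made after the data were seen found a tRNA gene within 100 bp of 166 optimal summits (23.7%) and of 0.248% of background summits. For snoRNA genes, whose products guide RNA modification, the counts were 52 optimal summits (7.43%) and 0.154% of the background. snRNA genes lay near 9 optimal summits. Together these 3 classes accounted for 227 optimal peaks (32.4%). With them left out, 77.0% of the other optimal summits were in promoter windows.

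Of the 20 strongest optimal peaks, 5 were mitochondrial and 10 of the 15 nuclear ones had a snoRNA or tRNA gene within 100 bp of the summit. The strongest peak in the whole list (signal 1792) had its summit at position 12423 of the mitochondrial genome, in the coding sequence of WBGene00010967, and the others lay at positions 4643 (WBGene00000829), 2197 (ND1, in the promoter window of WBGene00010960), 1237 (an rRNA gene, in the window of ND1) and 9280 (WBGene00010964, in the window of WBGene00010965). Each of these 5 had a peak in replicate 1 and none in replicate 2. The strongest nuclear peak was intergenic, on chromosome III from 8043766 to 8044192, 524 bp from the 5' end of K12H4.5. Introns held the peaks at frm-7 (chromosome V, 12303422 to 12303874, signal 743), cutl-18 (V, 11314034 to 11314402, signal 558) and pxn-1 (V, 8500389 to 8500707, signal 464), which encodes a peroxidasin. Each of these 3 summits lay within 100 bp of an annotated snoRNA gene (C51F7.3 and C51F7.4 at frm-7, T03F7.8 at cutl-18 and ZK994.7 at pxn-1). snoRNA genes also lay beside the intergenic summits 1328 bp from W03C9.1 and 1392 bp from str-56, the summits in the promoter windows of sre-23 and T02E1.2, and the summit in the window of mrps-28, a mitochondrial ribosomal protein gene. Of the tRNA genes, C40H5.t1 (X, 11757831 to 11757914) carried a peak of signal 557, 1201 bp from the 5' end of lact-7, and C04A11.t1 (X, 13665555 to 13665673) one of 435, 979 bp from C04A11.5. The remaining peaks were in the promoter windows of ears-2 and uncp-18, atx-2 and ecps-1, M01F1.9 (in an intron of M01F1.8), and mlcd-1 and idhg-1, with signals of 494, 427, 426 and 389. ears-2 encodes a glutamyl-tRNA synthetase, atx-2 the ortholog of the RNA-binding protein ataxin-2, and idhg-1 a subunit of isocitrate dehydrogenase.

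Cytosolic ribosomal protein genes were the list most often found near optimal peaks. Of its 78 members, 21 (26.9%, exact 95% interval 17.5% to 38.2%) had an optimal summit in the promoter window, against 601 of all 19985 protein-coding genes (3.01%). Its odds ratio against all other genes was 12.3 (7.02 to 20.7), with p = 8.6e-15 by two-sided Fisher's exact test and 1.46e-13 after Benjamini-Hochberg adjustment over the 17 lists fixed before the data were examined. Random lists matched on upstream length had 3.93 members with a peak on average, and the 21 observed were 5.35 times that (permutation test, adjusted p = 0.0017). The odds ratio was 6.33 among genes with a summit of the pooled list, a background chosen after the data were seen. With the stronger 350 peaks it was 7.14, and the list passed each time. The strongest of the peaks were at rpl-3 (signal 295; 128.6 in replicate 1 and 166 in replicate 2), rpl-15 (216; 109 and 105), rps-28 (210; 148 and 68.8) and rpl-20 (179; 90.2 and 83.1). Heat shock genes had a peak at 4 of 22 members (odds ratio 7.21, 1.77 to 22, Fisher's exact p = 0.00385, adjusted p = 0.0218). These were hsp-60 (177), hsp-110 (113), hsp-1 (106) and hsp-90 (105), which encode chaperones made constitutively in unstressed cells. Without replicate 1, with the peaks of replicate 2 alone, 3 of the 22 had a peak and the adjusted p of the exact test was 0.117. Against random lists matched on the length of the upstream intergenic region the permutation p was 0.0861 after adjustment, and over all alternatives the adjusted exact or permutation p ran from 0.0141 to 0.210.

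Chemoreceptor genes, which encode the large families of G protein-coupled receptors of sensory neurons, were found less often than other genes. Optimal summits lay in the windows of 8 of 1171 members (0.683%; odds ratio 0.211, 0.0906 to 0.421, Fisher's exact p = 2.73e-08, adjusted p = 2.32e-07). The strongest of these peaks were at sre-23 (601), sre-1 (257), sri-5 (172) and srh-16 (138). Among genes with a summit of the pooled list in their window, a background chosen after the data were seen, the odds ratio was 0.433 and the adjusted exact p was 0.0874, the highest over the alternatives (lowest 4.58e-09). The other 14 lists did not pass the test. Their members with a peak are named here after their values were seen. Histone genes had a peak at 4 of 72 members (his-37, his-67, his-68 and his-72), and nuclear receptor genes at 5 of 269 (nhr-255, nhr-41, nhr-48, nhr-47 and nhr-142). Collagen genes had one at 3 of 156 (col-185, col-71 and col-38), and neuropeptide and insulin-like genes at 2 of 140 (flp-23 and ins-39). Without replicate 2 the counts were 1 of 72 histone genes and 1 of 140 neuropeptide and insulin-like genes, and without replicate 1 they were 2 of 269 nuclear receptor genes and 0 of 24 panneuronal genes. Some of the named peaks lay at small RNA genes. With peaks at tRNA, snoRNA and snRNA genes left out, 3 of 269 nuclear receptor and 1 of 140 neuropeptide and insulin-like genes had one. So did 2 of 156 collagen and 5 of 1171 chemoreceptor genes, while histone genes stayed at 4 of 72. There was 1 peak each among the 24 panneuronal genes (syd-2) and the 16 germline genes (mex-1). None of the 88 homeobox genes had one (Fisher's exact test, adjusted p = 0.498), nor did any gene of the axon guidance and adhesion, muscle, pharynx, intestine, epidermis, AIY, or AIA and NSM lists. Neighbouring genes can share 1 peak, so the genes of a list are not fully independent, and the p-values are across genes, not replicates.

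**Figure D2:**
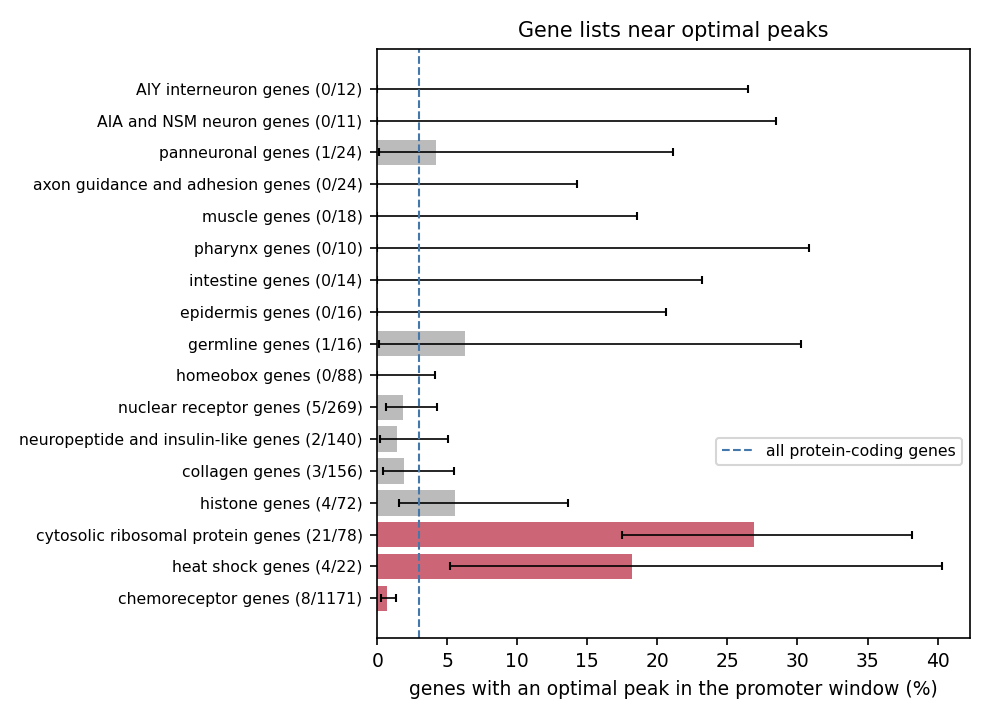
Share of each list's genes with an optimal summit in the promoter window (x axis, percent), with exact 95% binomial intervals as error bars and the counts beside each name; red bars passed the test at an adjusted p under 0.05, and the dashed line marks all protein-coding genes (3.01%). Ribosomal protein and heat shock genes lie above the line and chemoreceptor genes below it, while AIY, AIA and NSM genes have no peak in their windows.

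The genes of the AIY list and of the AIA and NSM list were examined 1 by 1. They were listed as genes of these neurons and need not all be targets of TTX-3. None of the 12 AIY genes and none of the 11 AIA and NSM genes had an optimal summit in its promoter window, with exact upper 95% limits of 26.5% and 28.5%, so the lists were too short to tell a share like that of all genes from a higher one. Weaker summits of the pooled list lay in the windows of 6 AIY genes: ttx-3 itself (signal 52.3, rank 1583), kal-1 (31.5), ser-2 (27.3), ceh-10 (25.7), unc-17 (25.6) and glc-3 (21). Those of ttx-3 and ceh-10 were found in both replicate lists, and that of unc-17 in replicate 2 alone, at rank 28096. Those of kal-1, ser-2 and glc-3 were in neither. The pooled list had a median signal of 26.9. The share of all genes with a summit of the pooled list is not given here, so these counts cannot be set against it. The windows of ceh-23, cho-1, flp-18, hen-1, mod-1 and sra-11 held none. Among the AIA and NSM genes, ins-1 (44.5), gcy-28 (38.8), ptps-1 (37.7), mgl-1 (29.8) and unc-86 (28.8) had a summit of the pooled list, while bas-1, cat-1, cat-4, mod-5, nlp-3 and tph-1 had none. Those of ins-1 and ptps-1 were found in both replicate lists, and those of gcy-28, mgl-1 and unc-86 in replicate 1 alone. Inside the genes themselves, 3 optimal peaks were present, each in an intron. That of ttx-3 (X, 11766231 to 11766680) had a signal of 141, with 78.5 in replicate 1 and 69.5 in replicate 2, and rank 207 in the pooled list. That of cat-1, which encodes the vesicular monoamine transporter, had a signal of 210 (105 and 111), and its summit lay within the tRNA gene E03E2.t1. That of ser-2, an amine receptor gene, had a signal of 111, was found in replicate 1 (53.3) but not in replicate 2, and lay within the tRNA gene C02D4.t1. With windows extended from 2000 bp upstream to the end of the gene, 2 of 12 AIY genes had a peak (Fisher's exact test, adjusted p = 0.333) and 1 of 11 AIA and NSM genes (adjusted p = 0.611), and under every other alternative both lists had an adjusted p of 1.

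**Figure D3:**
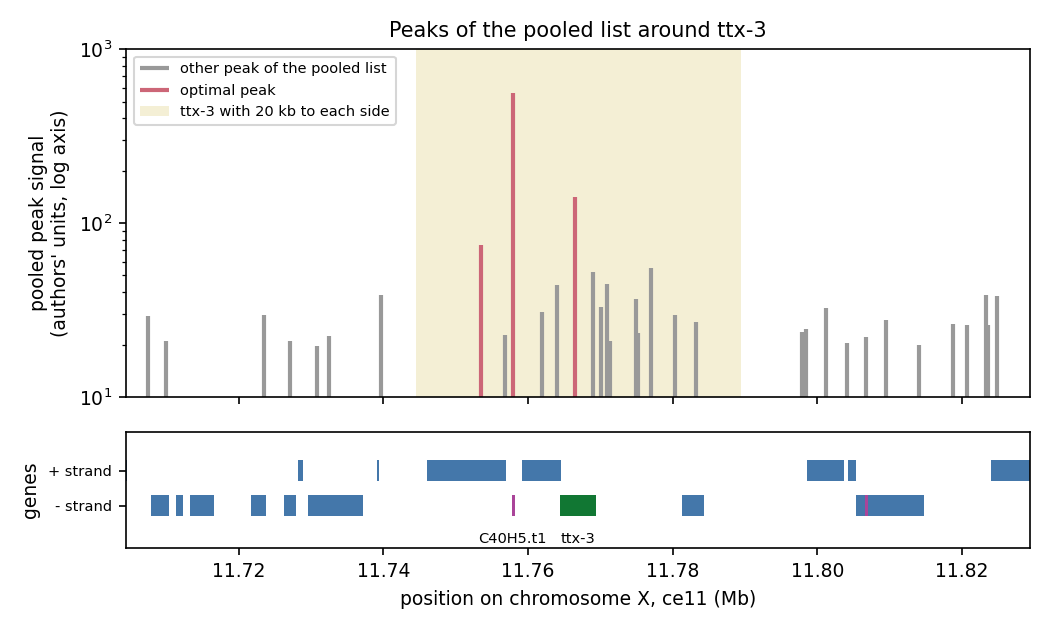
Signal of the peaks of the pooled list (y axis, authors' units, log axis) along chromosome X around ttx-3 (x axis, ce11 position in Mb), with optimal peaks in red, the 20 kb to each side of the gene shaded, and protein-coding genes (blue, ttx-3 in green) and tRNA genes (purple) by strand below. The optimal peaks in the shaded region are 3: the peak in the ttx-3 intron (signal 141), the stronger peak at the tRNA gene C40H5.t1 (557), and a weaker one (74.7).

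LIM homeodomain proteins recognise the core sequence TAATTA. It was found within 50 bp of 37 of 700 optimal summits (5.29%) and of 1000 of 14941 background summits (6.69%), a difference that did not pass the test (odds ratio 0.778, 0.540 to 1.09, two-sided Fisher's exact test p = 0.161). Optimal windows were richer in G and C than background windows (46.7% against 33%). Against an equal number of background windows matched on GC content, from 1 random draw, the odds ratio turned to 1.72 (0.976 to 3.09, Fisher's exact p = 0.0617). For the stronger 350 optimal peaks against all background windows, not matched on GC content, it was 0.581 (Fisher's exact p = 0.0494). Among all 6-mers, 737 were more frequent at optimal summits and 351 less frequent at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg over all 6-mers). The 4 of lowest p were depleted A and T runs: AAAATT was present at 20.6% of optimal and 57.6% of background summits, AAAAAT at 28.1% and 63.1%, AAATTT at 10.9% and 38.3%, and AAAAAA at 27% and 56.4%. The fifth, GCGCAC, was enriched, at 13.9% against 1.58% (odds ratio 10, 7.72 to 12.9, Fisher's exact test, adjusted p = 5.47e-50). With the matched background 75 6-mers were more frequent and 74 less frequent. By Fisher's exact test GCGCAC was enriched there too (13.9% against 4.57%, adjusted p = 1.12e-06), AAAATT was depleted (20.6% against 29.1%, adjusted p = 0.00827), and AAAAAT, AAATTT and AAAAAA no longer passed (adjusted p = 0.543, 0.107 and 1). The lowest exact p among enriched 6-mers then belonged to GTTCGA, named after its values were seen, at 15.4% against 4% (adjusted p = 4.66e-10). Without the peaks at tRNA, snoRNA and snRNA genes GTTCGA was at 5.07%, against 3.09% of the unmatched background, and did not pass (Fisher's exact test, adjusted p = 0.0585).

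Chromosome X carried 143 of the 700 optimal peaks (20.4%, exact 95% interval 17.5% to 23.6%), against 15.7% of background peaks (two-sided exact binomial test p = 0.000852). Chromosome V carried 12.6% of optimal and 16.8% of background peaks, and chromosome IV 14.7% and 18.2%. Genes for tRNAs are unevenly spread: of 612 nuclear ones, 276 (45.1%) were on chromosome X, as were 79 of the 165 optimal peaks at nuclear tRNA genes. Without the peaks at tRNA genes, an alternative chosen after the data were seen, the share on X was 12% and lay below the background (exact binomial p = 0.0200).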

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

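Replicate 1 listed 21 peaks on the mitochondrial genome, outside the nuclear chromatin that the comparisons are about. That is above 3, the limit for a count of 0 by counting error, which does not cover the spread between replicates. The limit assumes independent counts, which peaks on the same genome need not be, so it is no test of the difference. Replicate 2 listed 0, and 11 of these regions were among the optimal peaks. Their summits fell in 11 of the 14 1-kb bins of the mitochondrial genome.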

How the results depend on the processing

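Settings restricted to nuclear peaks, to promoter summits or to genes with a pooled summit, those without peaks at tRNA, snoRNA or snRNA genes, and the 1 to 1 GC matching that replaced up to 5 matched peaks, were chosen after seeing the data. The number of optimal peaks, the replicate overlap (43.0% to 72.9%) and the promoter share (52.1% to 77.0%) kept their direction and, where tested, their side of the threshold under the alternatives run. The rank correlation was 0.754 with summits within 50 bp. Among the gene lists, 3 passed in the main test and 1 among genes with a summit of the pooled list. Of 136 list values under alternatives, 130 kept their call. The other 6 lost it, 5 for heat shock genes and 1 for chemoreceptor genes (odds ratio 0.433). Most of the 136 values belong to lists that did not pass in the main test, and 8 lists had no member with a peak there. For those lists a kept call says little, and all the lost calls were in lists that had passed. The heat shock values were 4.76 to 7.13. They are odds ratios except against matched random lists, where 5.21 is the observed count over the mean count. The odds ratio of TAATTA turned to 1.72 against the GC-matched background, to 1.77 with up to 5 matched peaks each (exact p = 0.00746), to 1.08 without peaks at tRNA, snoRNA and snRNA genes, and to 2.98 with both changes. It was 0.581 for the stronger 350 peaks against the unmatched background. The counts of more and less frequent 6-mers were 75 and 74 against the GC-matched background, where fewer peaks were compared, and 469 were more frequent at promoter summits only. The share on X turned to 13.5% without peaks at tRNA, snoRNA and snRNA genes and to 12% without those at tRNA genes. Without replicate 1 or 2, the promoter share was 55.9% to 59.0%, the lists that passed 2 to 3, the odds ratio of TAATTA 0.734 to 0.823, the more frequent 6-mers 657 to 675, the less frequent ones 302 to 322, and the share on X 19.6% to 19.9%. Leaving out a replicate gives no value for the overlap, the correlation or the number of optimal peaks. No paired analysis was possible because there was 1 group. The causes of these changes were not tested except where the tests below give a value. Depth is unknown, so what it limits could not be assessed.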

Other observations

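The groups of genes in the next paragraph, the tests of TAATTA at peaks of small RNA and ribosomal protein genes, the test of single-copy tRNA genes against protein-coding genes, the share on X without tRNA peaks, and the GC-matched test of TAATTA away from small RNA genes were chosen after the results were seen. For the last of these, the odds ratio over all GC-matched peaks had already been seen, and its rule was tightened to the median over 100 draws after the first draw was seen.

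Other genes of the translation machinery and of mitochondria also carried optimal peaks. The lists were drawn up by gene symbol and can lack genes of their class. Translation initiation and elongation factor genes had one at 9 of 39 members (odds ratio 9.81, 4.08 to 21.3, Fisher's exact test, adjusted p = 2.15e-05 over 12 further lists), among them eif-3.C (signal 220) and eef-1A.1 (121). Genes with nuo, cox or atp symbols, which are part of the respiratory chain and ATP synthase genes, had one at 5 of 26 members (odds ratio 7.74, exact test, adjusted p = 0.00377), such as nuo-2 (133) and atp-2 (89.7). Mitochondrial ribosomal protein genes had one at 8 of 66 (odds ratio 4.50, exact test, adjusted p = 0.00377), such as mrps-28 (402) and mrpl-23 (131). Some of these peaks also counted for other classes. That of mrps-28 lay at a snoRNA gene, that of cox-6A near an snRNA gene, and that of mrpl-49 was also that of rpl-28. No value without such peaks is given here for these lists, so they are not independent of the earlier results. Aminoacyl-tRNA synthetase (2 of 31), proteasome subunit (2 of 33) and vacuolar ATPase genes (1 of 20) did not pass (exact test, adjusted p = 0.362, 0.362 and 0.549). C-type lectin (2 of 240), F-box genes with fbxa, fbxb or fbxc symbols (4 of 322), cytochrome P450 (0 of 74), UDP-glucuronosyltransferase (0 of 67), glutathione S-transferase (1 of 44) and basic helix-loop-helix genes (0 of 25) did not pass either. Among microRNA genes, 5 of 261 had an optimal summit within 100 bp, and 4 of these were mir-51 (375), mir-52 (160), mir-53 (81.6) and mir-54 (85.2) of the mir-51 family, which is abundant from the embryo onward, while mir-55 and mir-56 of that family had none. Among the snRNA genes with a peak were sls-2.1, sls-2.2 and sls-2.4, which encode the SL2 RNA used in trans-splicing, with signals of 142, 133 and 195.

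Optimal peaks gathered at tRNA, snoRNA, snRNA and ribosomal protein genes. TAATTA lay near 3 of 248 of these summits (1.21%, exact upper 95% limit 3.49%), so binding at that exact sequence is argued against for most of them. It was also near few of the other optimal peaks (7.52%) and background peaks (6.69%), so its absence does not set these peaks apart. Binding at other sequences was not tested. Whether TAATTA is rarer there than by GC content stays open (odds ratio 0.171 against all background peaks and 0.494, 0.0791 to 2.35, Fisher's exact p = 0.504, against GC-matched ones). The GC-matched value is from 1 random draw. Over 100 draws that odds ratio ran from 0.291 to infinity with a median of 0.747, and the exact p was under 0.05 in 0 draws. GC content is argued against as the whole cause: against the matched background the odds ratio of such an RNA gene within 100 bp was 47.5 (22.4 to 120). Reads shared between identical copies may add to the tRNA peaks, since 14% of single-copy and 31.1% of multicopy tRNA genes had one (Fisher's exact p = 3.82e-05), but the single-copy share has a lower 95% limit of 8.76%, above the 3.01% of all protein-coding genes. The windows differ: tRNA genes were counted by summits within 100 bp, and protein-coding genes by the promoter window. Single-copy means without an identical copy, so reads shared between similar tRNA genes were not tested. Recovery of highly transcribed or open chromatin whatever the factor remains a candidate explanation. The 26.9% of ribosomal protein genes with a peak is part of the pattern itself and cannot decide for it. No expression or accessibility data and no other factor were examined, and binding of TTX-3 there by another route was not tested.

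An optimal peak in its own intron made ttx-3 stand out among the listed AIY, AIA and NSM genes, since those in introns of ser-2 (AIY) and cat-1 (AIA and NSM) lay at tRNA genes. Extra copies of the ttx-3 region in the transgene are a candidate explanation for raised signal there. The 15 peaks of the pooled list within 20 kb of the gene had a median signal of 36.5 (bootstrap 95% interval 27 to 55.4, which holds the 95th percentile of windows, 32.5), at percentile 98.6 of 3451 windows of the same size on X, and the 19 peaks between 20 kb and 60 kb away had 25.8. Binding of TTX-3 to its own gene, which is known to maintain its own expression, stays open and was not tested apart from this. TAATTA was absent within 50 bp of the intronic summit.

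More optimal peaks lay on X than background peaks. The concentration of tRNA genes on X may account for this, since the share on X was 12% without the peaks at tRNA genes, below the 15.7% of background peaks. No biological explanation was tested.

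Away from tRNA, snoRNA and snRNA genes, TAATTA may mark homeodomain sites, as a hypothesis. It lay near 7.19% of these 473 summits and 2.54% of GC-matched background summits (odds ratio 2.98, 1.48 to 6.39, Fisher's exact test p = 0.00126), and its odds ratio ranked 2 among the 36 6-mers made of A and T alone, whose median was 1.27. TATTAA ranked first (3.12), and AAATAA, AATAAA, ATAAAA and AAAATA, with odds ratios of 1.80 to 2.12, had lower exact p-values than TAATTA, so a wider rise of A and T words stays open. Not all such words rose: AAATTT (odds ratio 0.539, Fisher's exact p = 0.000546) and AAAATT (0.693, Fisher's exact p = 0.0126) were less frequent. The matched background is a random draw. Over 100 draws the odds ratio ran from 1.59 to 6.03 with a median of 2.74, the exact p was under 0.05 in 95 draws, and TAATTA ranked 1 or 2 in 76 draws and 13 at worst. Which homeodomain protein such sites would belong to was not tested. The 473 summits include mitochondrial ones, and no value for the nuclear ones among them is given here. Over all optimal peaks TAATTA lay near 37 of 700 summits and near 34 of the 689 nuclear ones, so a few summits with it were mitochondrial.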
